A study of Mus musculus with 4 samples.

How the data were processed

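Heart RNA of mice was measured by strand-specific poly(A) RNA sequencing in 4 libraries, each a pool of 3 hearts at 12 weeks. Per the labels' protocols, total RNA was extracted from whole hearts, mRNA was captured on oligo-dT beads, and the library kit keeps the strand of origin. Per the submitters' processing notes, STAR and HTSeq were used with the mouse build mm10; versions, the counting mode and the strand setting were not given in the sources used here. The deposited values are raw read counts per RefSeq transcript, whole numbers without normalization, with 0 lines for unassigned reads. The files hold 41449 transcripts, of which 35328 are protein-coding and 6121 noncoding by their identifiers; mitochondrially encoded transcripts were not analysed here.

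Of the transcripts, 41252 matched a gene symbol and 197 did not. Counts were summed over the transcripts of a symbol, giving 25044 genes, of which 9344 had a count in any library. Transcripts of genes with more than 1 transcript made up 58.6% of the transcripts and held 14.3% of the counts; how the counting treated reads shared between such transcripts is unknown. Positions and exons came from GENCODE release M21 (GRCm38), which placed 40998 transcripts. A transcript was said to have an opposite-strand exon where an exon of another gene on the other strand overlaps one of its own, which held for 9257 transcripts. Genes that overlap another gene on the opposite strand are uncertain, since the strand setting of the counting is not stated, and a partner is named beside many of those in the text.

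The library totals were 170543 (NTG), 187365 (dC10mut), 176633 (control) and 186420 (tt). A single count equals between 5.34 and 5.86 CPM (counts scaled to a common library total), and the floor of 3 counts allowed by a count of 0 equals between 16.0 and 17.6 CPM. Intervals and floors cover counting error only, since PCR copies of a read are not independent molecules. The minimum of 1 CPM in a library of a pair, written in the design, therefore removes no gene with a count in that pair. For the common test, 1 CPM in at least 2 libraries kept 7360 of the 9344 genes with a count.

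Each group has 1 library, so the comparisons within pairs (dC10mut against NTG, tt against control, and control against NTG as a yardstick) used a rule of size with no p-value. Counts were scaled with TMM factors from edgeR over all 4 libraries (0.940, 0.999, 1.03 and 1.03 in the order above). The log2 ratio used a prior count of 0.5 scaled to library size, and its 95% interval was the exact Clopper-Pearson conditional binomial interval. A gene was counted as higher or lower when the absolute log2 ratio was at least 1, the interval excluded equality and a library of the pair reached 1 CPM. The difference between the pairs' ratios used the same size with a normal approximation of the counting interval. A common mutant difference was tested with edgeR's quasi-likelihood test with the pair as a block in genes at 1 CPM in at least 2 libraries, with Benjamini-Hochberg adjustment. A fold against 0 counts is a lower bound against 3 counts in that library.

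The design held 40 gene lists, 23 of pathways and 17 of cell type markers, fixed before the data were examined, as were the comparisons and the alternatives tried. For each list and pair, the median log2 ratio was given a bootstrap 95% interval over members and a percentile among 10000 random lists of the same size drawn within 20 bins of mean abundance; this describes these libraries and does not test the conditions. A percentile could be given for 32 lists per pair. In the HCM pair 5 lists stood at or above percentile 97.5 and 1 at or below percentile 2.5; in the DCM pair 2 and 7 did. Over members with at least 10 counts, a choice made after the data were seen, the numbers were 3 and 0, and 2 and 2, of 22 lists.

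Named genes were chosen by a rule fixed in advance: Mybpc3, the 8 largest positive and 8 largest negative ratios per pair among counted genes with an assigned symbol (no pseudogenes and no Gm, Rik or LOC symbols) at 5 CPM or more, up to 3 members per pathway list and up to 2 per cell type list by size of ratio, the 6 largest each way for the difference between pairs, up to 10 for the common difference and 5 each way for the control libraries. The rule took 107 genes in the HCM pair, of which 90 held under 10 counts, and 103 in the DCM pair, of which 83 did; most of those are left out of the text. Genes that differed at least 2-fold with at least 50 counts in a library, 59 in the HCM pair and 58 in the DCM pair, and list members with at least 5 counts were therefore also named, a choice made after their values were seen. Genes of lists that lie opposite another counted transcript were examined on the same footing. A few genes that meet these rules are not reported here, though they remain in the counts of genes and the list values.

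The ratio rule was tested on simulated counts with 200 genes changed by known folds. It recovered 49 of 100 genes changed 2-fold and 84 of 100 changed 4-fold in the HCM pair (7262 genes), and 41 and 91 of 100 in the DCM pair (7469 genes). The common test recovered 0 of 200 at the planned filter (7163 genes) and, among 1980 genes with at least 10 counts in 2 libraries, 41 of 100 changed 2-fold and 90 of 100 changed 4-fold, with 0 unchanged genes called. The simulated dispersion was 0.02, against 0.054 in the real data at the 10-count filter, so this recovery may be too high for these data.

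Alternatives fixed in advance were DESeq2 size factors, library totals, other count filters, a prior count of 5, the whole interval beyond 2-fold, no block, DESeq2's Wald test, means in place of medians, and the correlation without selected genes. Alternatives chosen after the data were seen were minimums of 10 or 50 counts, transcripts in place of genes, list counts raised to the floor of 3, and genes without an opposite-strand exon. Single libraries were not left out, since that leaves no comparison within the pair and a blocked common test that rests on the other pair alone. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.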

Results

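RNA from mouse hearts was sequenced in 4 libraries, 1 per group, each made from 3 hearts combined at 12 weeks of age. The study pairs each of 2 models carrying an altered cardiac myosin binding protein C, a thick-filament protein of the sarcomere, with a control. In the HCM (hypertrophic cardiomyopathy) pair, the library dC10mut came from cMyBP-CΔC10mut mice, transgenic for a 25-bp variant of MYBPC3, and the library NTG from nontransgenic mice; both are labelled C57BL/6. In the DCM (dilated cardiomyopathy) pair, the library tt came from cMyBP-C(t/t) mice and the library control from control mice; both are labelled FvB/N. The total counts were 170543 in NTG, 187365 in dC10mut, 176633 in control and 186420 in tt. Between 6725 and 6989 genes per library held a count, and between 1697 and 2001 held at least 10. With 1 library per group, no difference within a pair has a replicate check, and every interval given for a ratio covers counting error only. Counts of the Xist locus (Tsix and Xist) were 155 in dC10mut and 173 in tt, against 0 in NTG and 0 in control. A difference in sex between mutant and control pools thus cannot be told apart from genotype in either pair. Transcripts with an exon opposite an exon of another gene made up 22.6% of those placed on the annotation and held 69.1% of the counts in NTG, 66.2% in dC10mut, 67.4% in control and 65.6% in tt. For many of the genes below that have such a partner, the partner is given as the opposite-strand gene.

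Mybpc3, the gene behind both models (chromosome 2, 91118144 to 91136516, GRCm38), was within 2-fold in both pairs. It held 344 counts in NTG and 368 in dC10mut (log2 ratio -0.13, 95% interval -0.34 to 0.09). It held 266 counts in control and 412 in tt (log2 ratio 0.55, 0.32 to 0.78). The files count reads per transcript and not per allele, so this gene does not check the genotype labels.

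The question of the HCM pair is which genes differ between hearts with the 25-bp variant transgene and nontransgenic hearts. Mhrt, a heart noncoding RNA transcribed antisense to Myh7 (chromosome 14, 54968678 to 54974349), held 1778 counts in NTG and 6620 in dC10mut, which is 3.19-fold higher (log2 ratio 1.67, 1.60 to 1.75). The row of Myh7 itself, the beta myosin heavy chain gene on the other strand (which also faces Gm31251), held 27 and 11 counts (log2 ratio -1.48, -2.68 to -0.46). Genes of mitochondrial metabolism were among those higher in dC10mut. Hadh, a dehydrogenase of fatty acid oxidation, went from 47 to 140 counts (2.54-fold, log2 ratio 1.34, 0.86 to 1.86), and Cox8b, a subunit of cytochrome c oxidase, from 37 to 96 (2.21-fold). Pdk4, the kinase that inhibits pyruvate dehydrogenase, was 3.21-fold lower (78 and 28 counts, log2 ratio -1.68, -2.38 to -1.06), and Cox20, an assembly factor of cytochrome c oxidase with the opposite-strand gene Hnrnpu, was 3.24-fold lower (87 and 31 counts).

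**Figure D1:**
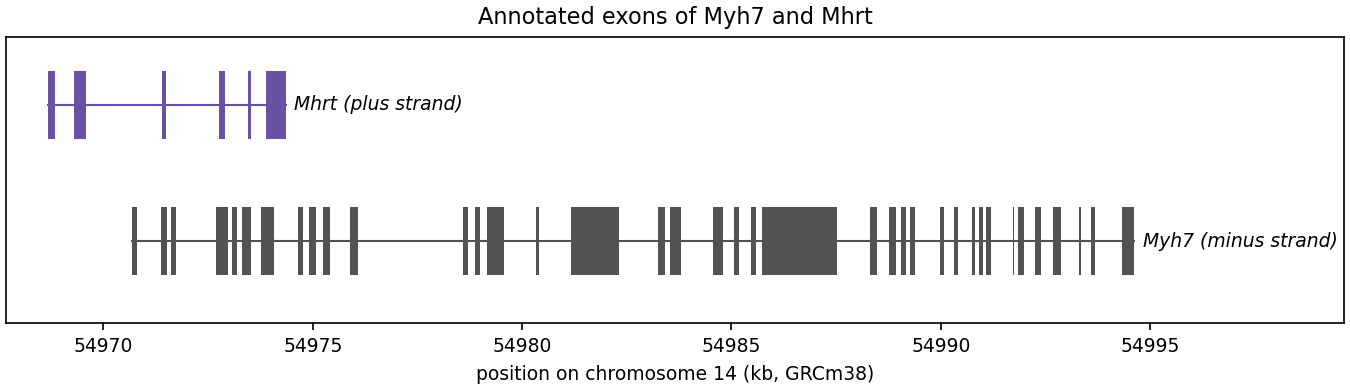
Annotated exons of Mhrt (plus strand) and Myh7 (minus strand) on chromosome 14 (position in kb, GRCm38); boxes are exons and lines the span of each gene. Mhrt spans 54968678 to 54974349 and overlaps the Myh7 span, which runs from 54970684 to 54994626.

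Among nuclear-encoded oxidative phosphorylation genes, 54 were measured in the HCM pair. Of these, 5 were at least 2-fold higher in dC10mut and 0 lower, and 43 of the 47 with at least 10 counts had a positive log2 ratio. The list median was 0.35 (bootstrap 95% interval over members 0.22 to 0.46), at percentile 100 of 10000 random lists of matched abundance. The 5 were Ndufb8 (2 and 14 counts), Ndufc2 (8 and 26), Ndufb6 (10 and 31, opposite-strand gene Smim27), Cox8b and Ndufa3 (13 and 32, opposite-strand gene Tfpt). Shorter transcripts had higher ratios in this pair (Spearman rho -0.20 between length and log2 ratio across 1059 genes without an opposite-strand exon), and members of this list had a median length of 763 bp against 2583 bp. Against lists matched on length as well as abundance, the 33 members with at least 10 counts and no opposite-strand exon (median 0.38) stood at percentile 91.3. Genes of ketone and branched-chain amino acid catabolism had a median of 0.44 (0.28 to 0.67, percentile 98.9), with a positive ratio in 12 of 14 members with at least 10 counts, among them Oxct1, the ketone body transferase (130 and 222 counts), and Hibadh (22 and 45). Cytosolic ribosomal proteins had a median of 0.28 (percentile 96.4) and a positive ratio in 17 of 18 such members (percentile 98.6 over these). Rplp0 (26 and 65 counts) and Rps9 (20 and 48) were at least 2-fold higher. In the DCM pair 12 of 19 such members of this list had a negative ratio. Lists other than oxidative phosphorylation were not matched on length. In the heat shock list 3 genes were at least 2-fold higher: Hspb8, a small heat shock protein (26 and 68 counts), the chaperonin Hspe1 (5 and 20, opposite-strand gene Hspd1) and Hspb2 (0 and 6, opposite-strand gene Cryab). The cardiac stress list had 2 lower genes, Myh7 and Myh7b (70 and 36 counts, opposite-strand gene Trpc4ap). Mhrt, which faces Myh7, went the other way (1778 and 6620 counts). Since the strand setting is not stated, the direction of Myh7 is uncertain. Nppa, the atrial natriuretic peptide gene (opposite-strand gene Gm13054), held 9 and 22 counts with an interval that spans equality (log2 ratio 1.03, -0.11 to 2.37). Extracellular matrix genes had a median of -0.56 (-1.40 to 0.30) over 25 members, of which 6 held at least 10 counts; Col8a1 (19 and 7 counts) was lower and Fstl1 (5 and 18) higher.

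Other genes that differed at least 2-fold in the HCM pair and held at least 50 counts included Ptgds, a prostaglandin D synthase (16 and 59 counts), Mrpl12, of the mitochondrial ribosome (29 and 80, opposite-strand gene Gm16755), Coq9, of coenzyme Q synthesis (40 and 103, opposite-strand gene Ciapin1), and Got1, an aspartate aminotransferase (40 and 99). Lower genes included Thra, a thyroid hormone receptor whose opposite-strand gene is the clock repressor Nr1d1 (575 and 302 counts, log2 ratio -1.15, -1.36 to -0.95), Masp2, a complement protease (94 and 31, opposite-strand gene Tardbp), and Nmrk2, a nicotinamide riboside kinase (61 and 30, opposite-strand gene Atcayos). Slc7a11, the cystine-glutamate exchanger, held 18 counts in NTG and 1 in dC10mut (log2 ratio -3.83, -9.77 to -1.73). The largest ratio of the pair was that of Rps18-ps4, a pseudogene (1 and 814 counts), and D630041G03Rik held 0 and 21. The rule fixed in advance leaves out pseudogenes and symbols of the Gm, Rik and LOC kinds, and the largest ratios it took belonged to genes with 0 counts in a library. Tsix, which lies opposite Xist, held 0 counts in NTG and 147 in dC10mut, at least 42.0-fold higher against a floor of 3 counts. Tob1 (10 counts), Gmfb, Hip1r, Mmachc and Zfp970 (9 each), Fuca1, Gab1 and Xist (8 each) held 0 in NTG. Evpl (13 counts in NTG), Esyt3 (10), Fbxo24, Muc20 and Xpa (8 each), Lrrc4b and Nrxn2 (7 each) and Asb14 (6) held 0 in dC10mut. Of these, Hip1r lies opposite Vps37b, Gab1 opposite Gm31105, Esyt3 opposite Gm37249, Fbxo24 opposite Gm36266, Muc20 opposite Muc4 and Nrxn2 opposite Gm14964.

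Across the 8033 genes measured in the HCM pair, 145 were at least 2-fold higher in dC10mut and 204 at least 2-fold lower. With the library totals in place of TMM scaling the numbers were 170 and 166, so the excess of lower genes depends on the scaling. It also lay in genes with an opposite-strand exon, of which 38 were higher and 113 lower; of genes without one, 104 were higher and 87 lower. In a separate simulation of 7262 genes with counting noise alone, 83 passed the same rule.

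The question of the DCM pair is which genes differ between hearts of cMyBP-C(t/t) mice and their controls. Kcnj11, the pore-forming subunit of the ATP-sensitive potassium channel, held 15 counts in control and 54 in tt (3.32-fold, log2 ratio 1.73, 0.92 to 2.70), and 5330439B14Rik, a noncoding transcript whose opposite-strand gene Abcc9 encodes the regulatory subunit of that channel but held 0 counts, held 54 and 282 (4.90-fold). Nppa held 60 counts in control and 16 in tt (3.87-fold lower, log2 ratio -1.95, -2.88 to -1.17), and Ankrd1, a stress-responsive ankyrin repeat gene of heart muscle, 609 and 321 (2.01-fold lower, log2 ratio -1.01, -1.21 to -0.81). Pdk4 was 2.58-fold lower (113 and 46 counts, log2 ratio -1.37, -1.91 to -0.87) and Cox20 2.37-fold lower (133 and 59 counts). A630019I02Rik, a noncoding transcript with the opposite-strand gene Cmya5, held 70 and 1273 counts and was 17.1-fold higher (log2 ratio 4.09, 3.75 to 4.47).

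The ion channel and conduction list had a median of 0.84 in the DCM pair (-0.07 to 1.26, percentile 99.7) over 21 members, and of -0.08 with every count raised to the floor of 3. All 5 members with at least 10 counts had positive ratios (median 1.26, percentile 99.3), with Kcnj11 and Kcnq1 (2 and 11 counts, opposite-strand gene Kcnq1ot1) at least 2-fold higher, and Gja1, which encodes connexin 43, at 80 and 107 counts. Gm9899, opposite the potassium channel gene Kcnk3, held 73 and 209 counts. In ketone and branched-chain amino acid catabolism, Mmut, the methylmalonyl-CoA mutase, was the 1 higher member (15 and 39 counts, opposite-strand gene Cenpq), and the list median was 0.13 (percentile 81.4), or 0.01 (percentile 58.6) over members with at least 10 counts. Of transcripts outside the list that face its members, BC037032, opposite Oxct1, held 131 and 346 counts and Bbof1, opposite Aldh6a1, 152 and 337, while Oxct1 held 184 and 274 and Aldh6a1 0 and 1. Oxidative phosphorylation genes had a median of -0.31 (-0.40 to -0.09, percentile 0.61), with 0 members at least 2-fold higher and 2 lower, Ndufb3 (39 and 12 counts) and Ndufc1 (21 and 10). A negative ratio was found in 34 of the 45 members with at least 10 counts, whose median of -0.24 stood at percentile 5.31. Against lists matched on length too, the 31 of them without an opposite-strand exon (median -0.31) stood at percentile 16.0. Longer transcripts had higher ratios in this pair (Spearman rho 0.29 across 1155 genes without an opposite-strand exon). In the sarcomere list, Myom2, an M-band protein, was higher (88 and 217 counts, log2 ratio 1.22, 0.86 to 1.59).

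Endothelial markers had a median of -0.94 in the DCM pair (-1.20 to 0.13, percentile 0.03) over 12 members. All 5 with at least 10 counts had negative ratios, among them Fabp4, a fatty acid binding protein of capillary endothelium and fat cells (203 and 102 counts, log2 ratio -1.07, -1.43 to -0.73), Kdr, a receptor of vascular endothelial growth factor (27 and 11), and Cdh5 (25 and 15). Every other cell type list with a median in this pair also had a negative one, though several rested on few counts. With every count raised to the floor of 3, the fibroblast, activated fibroblast, lymphatic endothelial and lymphocyte medians were each -0.08. Those of adipocyte, skeletal muscle, atrial and endothelial markers were -0.58, -0.53, -0.21 and -0.86. Without the floor, the lymphocyte median stood at percentile 47.6. Pericyte and smooth muscle markers had a median of -0.42 (percentile 11.8), and 5 of their 6 members with at least 10 counts had negative ratios. Macrophage markers had -1.78 (percentile 0), or -0.08 with every count raised to the floor of 3. Of the macrophage markers, Lyz2, or lysozyme, was the 1 member with at least 10 counts, at 28 and 5. Immediate early genes had a median of -0.79 (percentile 0.35), and the 6 members with at least 10 counts a median of -0.52 (percentile 9.64), with Ccn1 (13 and 2 counts) at least 2-fold lower, while Dusp1 held 30 and 60 counts. In the interferon list B2m was lower (49 and 25 counts), in the oxidative stress list Gsta4 (18 and 5), in the integrated stress list Gars (14 and 3) and Slc7a11 (12 and 0), and in the extracellular matrix list Col1a2 (11 and 2). The latter list also held a higher gene, Col4a2 (16 and 36, opposite-strand gene Gm15419).

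Other abundant genes that differed in the DCM pair were Lrrc15, a leucine-rich repeat membrane protein (547 and 1705 counts, 2.94-fold, log2 ratio 1.56, 1.42 to 1.70), Slc3a1, of cystine transport (159 and 481, opposite-strand gene Prepl) and Gm16090, opposite the desmosomal gene Dsg2 (48 and 179). Of the largest ratios among symbols the fixed rule admits, Tsix held 0 and 159 counts, at least 50.1-fold higher, and Xist 0 and 14. Pitpnm2 held 1 and 55 (log2 ratio 5.12, 3.16 to 11.03). Rnf168 (12 counts), Agps, Iqgap1 (opposite-strand gene Gm44649) and Znrf2 (8 each) and B4galt6 (7) held 0 in control. Sycp1 (15 counts), Ddx3y, on the Y chromosome (14), Slc7a11 (12), Cyp27a1 (10), Upf3a (9), Fads3 and Polr3c (8 each) and Carmn (7) held 0 in tt.

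Across the 8248 genes measured in the DCM pair, 222 were at least 2-fold higher in tt and 130 at least 2-fold lower. In a separate simulation of 7469 genes with counting noise alone, 96 passed the same rule.

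**Figure D2:**
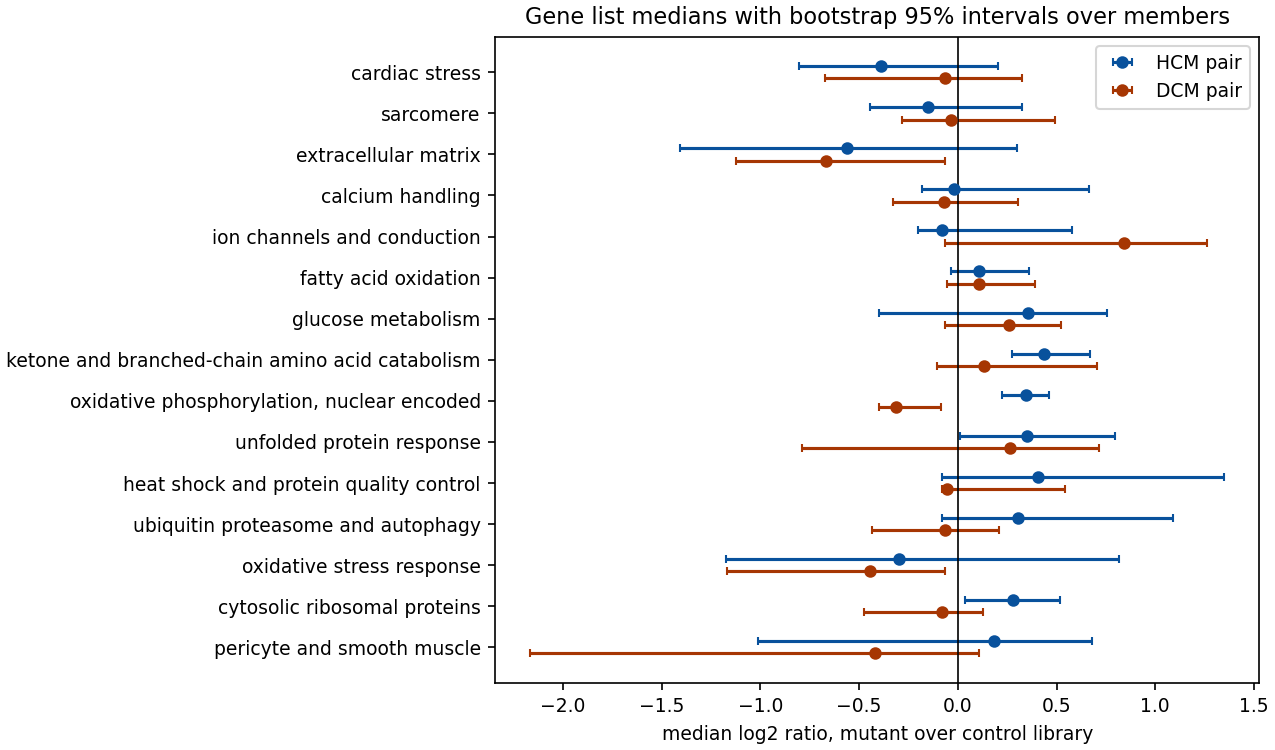
Median log2 ratio of mutant over control library for the 15 gene lists with at least 5 members of 10 or more counts in both pairs; points are list medians and bars bootstrap 95% intervals over members. The oxidative phosphorylation medians lie at 0.35 in the HCM pair and -0.31 in the DCM pair.

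The NTG and control libraries give a yardstick for differences unrelated to the models, though not one matched to the pairs. They differ in their strain label, which the libraries of a pair share. Both held 0 Xist-locus counts, while within each pair these counts differed. Nppa was 5.65-fold higher in control than in NTG (60 and 9 counts, 95% interval of the log2 ratio 1.54 to 3.75) and Ankrd1 2.36-fold higher (609 and 227). Mhrt was 2.89-fold lower in control (698 and 1778 counts), Slc3a1 3.13-fold lower (159 and 440), A630019I02Rik 3.93-fold lower (70 and 244), Lrrc15 2.03-fold lower (547 and 980) and Myom2 2.12-fold lower (88 and 165). The plot of normalised counts of named genes sets several of them beside tt and dC10mut. Rps18-ps4 held 641 counts in control and 1 in NTG. Among symbols the fixed rule admits, the largest ratios were those of Sycp1 (15 counts), Mmachc (10), Mrpl15 (9), Gpr157 (8) and Chad (7), at 0 in NTG, and of Ppp1r13b (10), Hoxaas2 (opposite-strand gene Hoxa3) and Pank3 (8 each) and Snx18 (7), at 0 in control, with Pitpnm2 at 1 in control and 42 in NTG. In all, 252 of 8152 genes were at least 2-fold apart, 114 higher and 138 lower in control.

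**Figure D3:**
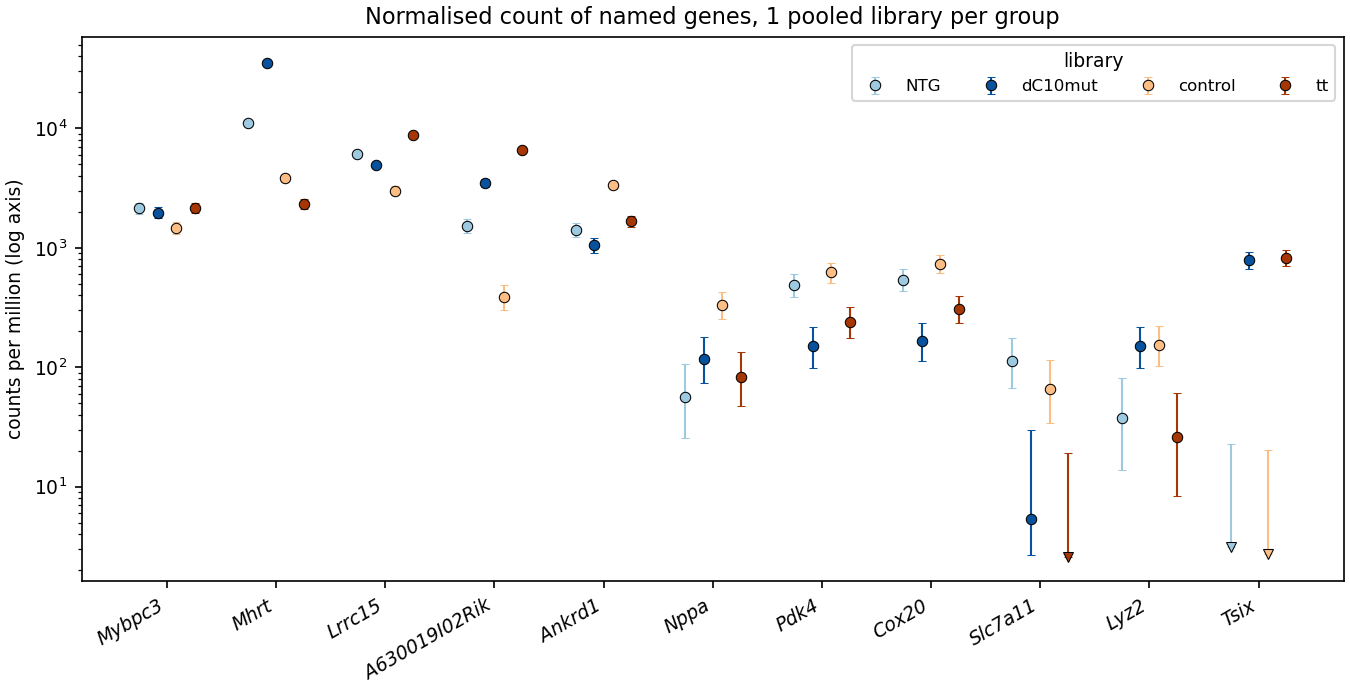
Normalised count (CPM, log axis) of 11 named genes in the 4 libraries, 1 pooled library per group; bars are exact 95% Poisson intervals for counting error, cut at 0.5 counts, and triangles mark 0 counts, drawn at 0.5. Mhrt lies at 35350 CPM in dC10mut, and Tsix at 785 in dC10mut and 826 in tt with 0 counts in both control libraries.

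Setting the pairs against each other asks whether both models move the same genes. Mhrt was the most abundant gene with opposite directions: its log2 ratio was 1.67 in the HCM pair and -0.72 in the DCM pair. Lyz2 was higher in the HCM pair (6 and 28 counts) and lower in the DCM pair (28 and 5), and Lrrc15 and Myom2, higher in the DCM pair, had ratios of -0.31 and -0.52 in the HCM pair. Genes at least 2-fold lower in both pairs numbered 15, where independent lists would share 2.84, and included Pdk4, Cox20, Slc7a11, the proliferation marker Mki67 (5 and 0 counts; 7 and 0), the transcription factor gene Stat6 (21 and 6; 30 and 12, opposite-strand gene Nab2), Leng1 (log2 ratios -1.38 and -1.37, opposite-strand gene Cnot3) and Phox2a (69 and 33; 72 and 30, opposite-strand gene Inppl1). Genes higher in both numbered 10, against 3.44, and included Gpr22, an orphan receptor (5 and 21; 8 and 21), Osbp, an oxysterol binding protein (3 and 18; 3 and 16), A630019I02Rik, Tsix and Xist. Among genes with at least 10 counts the shared numbers were 14 lower, against 7.13, and 10 higher, against 8.60. Opposite directions also met more often than independent lists would: 5 genes were higher in the HCM pair and lower in the DCM pair, against 2.02, and 9 the reverse, against 4.85. Among genes with at least 10 counts those numbers were 5, against 5.24, and 9, against 11.7.

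Across 9344 genes, which are not independent replicates, the log2 ratios of the pairs had a Pearson r of 0.050 and a Spearman rho of 0.042; across the 633 genes with at least 50 counts, a filter chosen after the data were seen, r was 0.40 and rho 0.32. The ratio was at least 2-fold higher in the DCM pair for 228 genes and at least 2-fold lower for 171, which is 57.1% higher; scaling by library totals gave 186 and 211, or 46.9% higher.

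**Figure D4:**
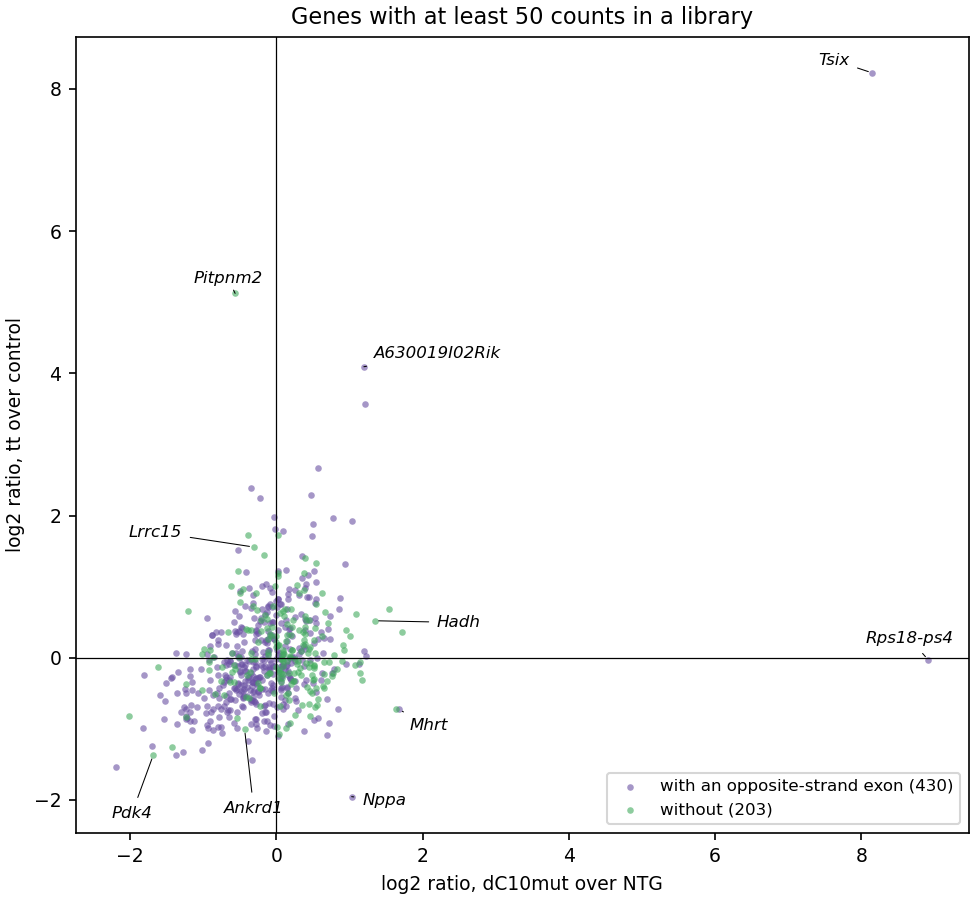
Log2 ratio in the DCM pair (tt over control) against the log2 ratio in the HCM pair (dC10mut over NTG) for the 633 genes with at least 50 counts in a library, coloured by the presence of an opposite-strand exon (430 with, 203 without). Mhrt lies at 1.67 and -0.72, A630019I02Rik at 1.20 and 4.09, and Pdk4 at -1.68 and -1.37.

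A difference between mutant and control libraries common to both pairs was tested with edgeR's quasi-likelihood test with the pair as a block, which leaves 1 residual degree of freedom. At a Benjamini-Hochberg adjusted p under 0.05, 8 genes were higher in the mutant libraries and 5 lower, of 7360 tested. Pdk4 fell by 1.54 on the log2 scale (SE 0.368, adjusted p 0.0257 by edgeR), Cox20 fell by 1.48 (SE 0.360, adjusted p 0.0311 by edgeR) and Slc7a11 fell by 4.78 (SE 0.912, adjusted p 0.000307 by edgeR), each lower in 2 of 2 mutant libraries. Megf11 (18 and 5 counts; 20 and 3) and the Y-linked Ddx3y (1 and 0; 14 and 0) were the other lower genes. The higher genes were A630019I02Rik (log2 difference 2.58, SE 0.330, adjusted p 1.98e-11 by edgeR), Tsix, Xist, D630041G03Rik, Pcdhga12, E130215H24Rik, 5330439B14Rik and Rps18-ps4; the last differed in the HCM pair alone, with 1 and 814 counts there and 641 and 665 in the DCM pair. Of the 13 genes, 8 have an opposite-strand exon; Pcdhga12 lies opposite Gm26672, E130215H24Rik opposite Acss1 and Rps18-ps4 opposite Gm10260. Tsix alone was called without the block, with 454 of 7360 genes at an unadjusted p under 0.05 by edgeR. It was also alone with at least 10 counts in 2 libraries, a filter chosen after the data were seen, with 156 of 1972 at an unadjusted p under 0.05 by edgeR. DESeq2's Wald test with the same block called 0 genes, with 41 of 9344 at an unadjusted p under 0.05, where edgeR had 320 of 7360 against 368 by chance. In simulated data edgeR recovered 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold at this filter, so a gene that was not called says little. The simulated fit had 4.03 prior degrees of freedom, while the fit that called the 13 genes had an infinite prior, so the simulation does not check those calls; the fits without the block and at 10 counts, where Tsix alone was called, had 5.18 and 5.99.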

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

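The comparison of directions between the pairs was run after the ratios were seen, while the tests of transcript length and of genes without an opposite-strand exon were written down before their results were seen. Each result below is a difference between the log2 ratios of the 2 pairs, DCM minus HCM, for a gene or list whose counting interval excludes equality in both pairs with opposite signs, or a list whose bootstrap intervals do. The differences rest on counting or bootstrap intervals in 1 library per group, and no test across replicates was possible. Among genes with at least 10 counts, opposite 2-fold calls were no more frequent than independent lists would give (5 against 5.24, and 9 against 11.7). Several differences rest on few counts. In NTG, dC10mut, control and tt, Fbxo7 held 13, 2, 4 and 17, Mrm1 7, 21, 8 and 1, and Sf3a1 13, 5, 2 and 11.

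Of heart muscle and metabolic genes, Mhrt differed by -2.40, Tnnc1 by -1.10, Myom2 by 1.74, Cox7a1 by -1.08, Ndufa6 by -1.15, Acot13 by -1.28, Atp5md by -2.69, Chchd10 by -1.57 and Phyhip by 2.34. Of immune, clock and transport genes, Lyz2 differed by -4.37, Ptgds by -2.36, Nr1d1 by 1.19, Slc3a1 by 2.04, Slc9a4 by -4.72, Clic3 by 3.12, Lrrc15 by 1.87 and Slfn5os by 1.05. Further genes were Gabarap (-2.90), Bace1 (2.41), Fbxo7 (4.52), Mrm1 (-3.86), Sf3a1 (3.63), Msmp (1.35), Hils1 (2.82), Nrp (-1.27) and Fam151a (1.05). Less characterised transcripts were 1810062O18Rik (2.07), 4930513N10Rik (-1.64), 4932702P03Rik (1.10), C230072F16Rik (3.14), C920021L13Rik (-1.78), Gm13205 (1.08), Gm43915 (2.84) and Gm4814 (1.22). The list medians differed by -1.97 for lymphatic endothelial markers, of which 3 were measured and 0 held at least 10 counts, and by -3.33 for macrophage markers, of which Lyz2 alone held at least 10; with every count raised to the floor of 3, the macrophage medians were -0.22 and -0.08 in the HCM and DCM pairs.

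The oxidative phosphorylation list differed by -0.66, with medians of 0.35 in the HCM pair and -0.31 in the DCM pair. A general shift of genes without an opposite-strand exon does not account for it: against abundance-matched genes of that class the members in it with at least 10 counts stood at percentile 99.7 in the HCM pair and 0.13 in the DCM pair. A trend with transcript length remains a candidate explanation: against genes matched on length as well, its members without such an exon and with at least 10 counts (33 and 31, medians 0.38 and -0.31) stood at percentile 91.3 and 16.0, inside the central 95% of matched lists. Matching left 0.17 and -0.10 of those medians over, and the matched genes were still longer than the members by 0.25 on the log2 scale. A difference between the models, which the design names, stays open and untested, since length and model cannot be separated with 1 library per group.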

How the results depend on the processing

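Counts of genes and the correlation kept within 1.5 times the reported value, or within its interval, in 61 of 88 alternatives; list medians did so in 348 of 364 and ratios of named genes in 1067 of 1071. Of medians whose interval excludes 0, only the macrophage median of the HCM pair changed sign, from 1.55 to -0.22 with every count raised to the floor of 3, chosen after seeing the data. Some medians whose interval spans 0 also changed sign; with at least 10 counts, chosen after seeing the data, the HCM pair's circadian clock median went from -0.18 to 0.63 and its fibroblast median from -0.30 to 0.60. The balance of higher and lower genes did turn: library totals gave 170 higher and 166 lower in the HCM pair, and 186 and 211 for the difference between pairs. A prior count of 5 gave 102 genes higher and 56 lower in the DCM pair's ratio, and a correlation of 0.105. Requiring the whole interval beyond 2-fold, which is stricter by construction, gave 6 higher and 17 lower in the HCM pair, 29 and 9 in the DCM pair, 15 apart between the control libraries, and 27 and 12 for the difference between pairs. Keeping genes without an opposite-strand exon, chosen after seeing the data and leaving fewer genes, gave 104 higher and 87 lower in the HCM pair, 106 higher and 73 lower in the DCM pair, 144 apart between the control libraries and 102 higher for the difference between pairs. The correlation was 0.0857 at 20 CPM and 0.400 at 50 counts, the latter chosen after seeing the data.

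For the common difference, dropping the block called 1 gene higher (Tsix) and 0 lower, with 454 of 7360 genes at an unadjusted p under 0.05 by edgeR. DESeq2's Wald test called 0 higher and 0 lower, with 41 at an unadjusted p under 0.05. DESeq2 size factors in edgeR called 3 lower, and testing every gene with a count called 3 lower. Of alternatives chosen after seeing the data, at least 10 counts in 2 libraries called 1 higher and 0 lower, with 156 of 1972 genes at an unadjusted p under 0.05 by edgeR, and genes without an opposite-strand exon gave 0 higher and 1 lower (Slc7a11), with 157 of 4849 at an unadjusted p under 0.05 by edgeR. Beyond settings that test fewer genes, the cause was not tested. The groups have 1 library each, so beyond the pair block of the main fit there is nothing to pair. Leaving out a library was not tried, since the blocked fit would then rest on 1 pair. The alternatives at 1 and 5 CPM, without a filter in the pairs, and without mitochondrial genes changed nothing by construction. Of 100 simulated 2-fold changes, 49 and 41 were found in the HCM and DCM pairs. The rule's threshold equals that change, so many would be missed at any depth.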

Other observations

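The tests of strand, of reads counted without regard to strand and of sex in this part were chosen only after the pattern was seen; the test without the 100 most abundant transcripts was written before. An earlier test of reads counted without regard to strand used the share of counts itself and was dropped, since it restated the pattern.

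The circadian clock list stood at percentile 39.4 in the HCM pair and 80.5 in the DCM pair; over its 3 members with at least 10 counts the percentiles were 97.4 and 87.1, with a median of 0.63 in the HCM pair against -0.18 over all members. Dbp, a clock output transcription factor (opposite-strand gene Sphk2), held 18 counts in NTG and 49 in dC10mut and 35 and 23 in the DCM pair, and Nr1d1, a repressor of the clock (opposite-strand gene Thra), held 194 and 128, and 137 and 187. Smooth muscle and vascular genes in the HCM pair included Acta2, smooth muscle actin (6 and 24 counts), the water channel gene Aqp1 (8 and 29) and Notch3 (34 and 11, opposite-strand gene Gm17276). Acta2 held 24 counts in control and 17 in tt, and Aqp1 30 and 17, so NTG was the lowest library for both. Apoa2, a gene of the liver marker list, held 113 and 203 counts in the HCM pair and 70 and 140 in the DCM pair, within 2-fold in both.

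Of 1401 genes with at least 20 counts in a library, 6 split the libraries at least 2-fold by strain label (Mhrt among them), 16 by mutant against control, and 6 into NTG and tt against dC10mut and control. A single library stood apart in 24 genes for NTG, 32 for dC10mut, 35 for control and 26 for tt. Rps18-ps4 (opposite-strand gene Gm10260) held 1 count in NTG and 814, 641 and 665 in dC10mut, control and tt.

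Counts of the Xist locus, Tsix and Xist together, lay in the mutant libraries alone, 328 against 0, and Y-linked counts in the control libraries alone, 16 against 0. Counting error does not account for this, since the exact 95% interval of the mutant share of Xist-locus counts begins at 98.9%, above the 52.6% of the depth. Female hearts in the tt pool and none in its control pool are a candidate explanation for the DCM pair, where the control library held 15 Y-linked counts and tt 0. In the HCM pair dC10mut held 155 Xist-locus counts and NTG 0, the same direction as in the DCM pair. NTG held 1 Y-linked count, under the floor of 3, so the Y-linked counts leave the sex of that pool open. Whether sex underlies the other 10 genes of the common difference, or other differences within the pairs, cannot be told apart from genotype, because each genotype has 1 pool.

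Between 65.6% and 69.1% of each library's counts lay on transcripts with an opposite-strand exon, which make up 22.6% of transcripts; without the 100 most abundant transcripts the lowest share was 53.2%, which goes against a few abundant transcripts as the whole account. Reads counted without regard to strand would, in HTSeq's default mode, be dropped where exons overlap. Transcripts sharing at least 95% of their exon bases held at least 10 counts in 23.9% (17 of 71, exact 95% interval 14.6 to 35.5%), against 2979 of 14921 sharing none (19.3 to 20.6%). Most of the 71 are microRNA transcripts, so the comparison mixes kinds of RNA and leaves this open. Of the others, Msmp (602 counts over all libraries), Bricd5 (488) and Lrrc14b (387) held many, while Il4i1 (9) and Ptprcap (2) held few. Reads may have been assigned to the strand opposite to the transcribed one, as a stranded kit counted with the reverse setting would give. This was tested first in list genes that face another transcript of the files, even at 0 counts. The facing row was ahead in 51.2% (42 of 82, exact 95% interval 39.9 to 62.4%), which decides nothing. Each gene weighed the same there, whatever its depth or the length of the overlap. In counts over all libraries, the facing rows held 79870 and the genes' own rows 27357. Of the facing counts, 49458 lay in Map3k15, opposite Pdha1 (687). Other pairs went the other way, such as Myl2 (10934) facing Ccdc63 (1). A further test, chosen because the first was undecided, found at least 10 counts in 54.8% of 217 noncoding transcripts sharing over 300 exon bases with the opposite strand (48.0 to 61.6%), against 59 of 3012 sharing none (1.49 to 2.52%), a gradient that is in line with wrong-strand assignment and that true antisense transcription near active genes could also give. Wrong-strand assignment therefore remains a hypothesis. Under it a row such as Mhrt might hold reads of Myh7, and Tsix (306 counts over all libraries) reads of Xist (22).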
